A study of Mus musculus with 9 samples.

How the data were processed

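The series holds 9 RNA sequencing libraries of mouse hippocampus. Per the labels, 3 come from sham-operated mice, 3 from mice after cecal ligation and puncture (CLP, a surgical model of abdominal sepsis) and 3 from CLP mice given the flavonoid extract of Cuscuta chinensis (CLP plus extract). The sample names and table columns call these groups CTL, SAE and CCLF, and the series record describes CTL as the sham operation. Here "labelled sham" stands for CTL, "labelled CLP" for SAE and "labelled CLP plus extract" for CCLF. Only the deposited table of whole-number transcript counts was used. The submitters' processing notes name fastp and Salmon. Their versions, settings, transcript index and genome build are not given in the sources used here. The raw reads were not analysed here.

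The table lists 120312 RefSeq transcripts, and all 120312 were matched to gene names with the RefSeq table of assembly GRCm38.p6, which served for names only. Counts were summed to 38911 genes, of which 22846 had at least 1 count. Library totals ran from 4626519 to 4895474 counts. At this depth genes with few counts could not be tested, and a fold was limited by counting error where a group held 0 to 3 counts. The 13 transcripts of mitochondrially encoded proteins had 0 counts in every library.

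Genes were kept with edgeR's filterByExpr by group, which left 8479 tested genes. Libraries were scaled by the trimmed mean of M values (factors 0.984 to 1.015). All 9 libraries were fitted together with edgeR's quasi-likelihood F test with robust estimation. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Each log2 fold is given ± an approximate standard error (SE), the size of the log2 fold divided by the square root of its F statistic. Expression is given on edgeR's CPM scale with these factors applied, as mean ± standard deviation (SD, n = 3 libraries per group). Every fold labelled CLP against sham is CLP minus sham.

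Gene lists were written from general knowledge of the field before the data were examined, as were the comparisons, their tests and the first set of alternatives. Of the list genes, 875 of 888 were found in the table. Lists with at least 5 tested members, 44 in all, were tested with limma's camera on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the 44 lists. The alternative with an estimated correlation is given beside each call it ends. Lists of 8 kinds had fewer than 5 tested members and were only counted. A member was counted when its p-value adjusted over all tested genes was under 0.05. Numbers of members are out of those tested, and large parts of some lists could not be tested. Of the homeostatic microglia list 8 of 16 members in the table were tested, of A1 genes 5 of 12 and of A2 genes 6 of 12. Of acute-phase genes 11 of 23 were tested, and of MHC class I and complement genes 7 of 13 each. Where adjusting over the list alone changed a number, both numbers are given.

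Genes named in the text follow a rule. They are up to 6 of the highest and 6 of the lowest folds among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 members with the smallest p-values of each described list, the genes of the pathway in the series title, and a short set of inflammation and sex-linked genes. Genes named outside this rule were chosen after values were seen. They are Actb, Camk2a, Cst3, Gapdh, Gria2, Grin1, Mbp, Slc17a7, Snap25 and Syn1.

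Where a group had 0 counts a fold is given as "at least", against a floor of 3 counts over the group. Where a group had 1 to 3 counts the ratio of CPM is given with its 95% counting interval. These floors and intervals cover counting error only.

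The alternatives were DESeq2 size factors, the DESeq2 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit of only the 6 libraries compared, replicate number as a block, thinning to the smallest total, removal of mitochondrial, haemoglobin and choroid plexus genes, and each library left out in turn. For lists, an estimated correlation and limma's fry were added. Chosen after values were seen were a fit of genes with only 1 RefSeq transcript, list tests in the 6 libraries labelled sham and CLP, the tests of gene families, and every test in the closing section: those of the extract columns, of the labels, of genes with several transcripts and of splits of the libraries. No library was left out of the fit reported. The calling steps were tested on simulated data: in counts with known changes, 81.6% of 98 genes changed 2-fold and 99% of 100 genes changed 4-fold were recovered, with 11 false calls. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.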

Results

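Lcn2, which encodes an iron-binding acute-phase protein, was among the most lowered genes in the libraries labelled CLP: 2.33 ± 0.955 CPM (mean ± SD, n = 3) against 2960 ± 176 in those labelled sham (log2 fold −10.3 ± 0.48, adjusted p = 1.77e-05 by edgeR's quasi-likelihood test). Its counts were 6 to 14 in the libraries labelled CLP and 13246 to 14822 in those labelled sham. The chemokine gene Cxcl10 fell with it, from 869 ± 583 to 1.56 ± 0.821 CPM (log2 fold −9.11 ± 1.63, adjusted p = 0.00433). With limma-voom the adjusted p of Cxcl10 was 0.161, in a range of 5.16e-19 to 0.161 over its alternatives. Ccl2, another chemokine gene, fell from 65.4 ± 53.8 to 0.355 ± 0.325 CPM (log2 fold −7.43 ± 1.31, adjusted p = 0.00375). With limma-voom the adjusted p of Ccl2 was 0.0517, in a range of 4.35e-12 to 0.0517. Marco, a macrophage scavenger receptor gene, was 1540 times higher in sham-labelled libraries (counting interval 527 to 7470), and limma-voom gave 0.0757 in a range of 2.55e-20 to 0.0757. Cxcl2 was at least 156-fold higher there and Tnfsf8 at least 52.5-fold, while Mmp3 had a ratio of 1520 (272 to 60000).

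Genes higher in the libraries labelled CLP had smaller folds. Gkn3, an endothelial gene, rose from 0.351 ± 0.115 to 10.2 ± 2.83 CPM (n = 3, log2 fold 4.76 ± 0.77, adjusted p = 0.00089). Bicd2, a dynein adaptor gene, rose to 8.38 ± 0.651 from 0.49 ± 0.235 CPM (4.01 ± 0.3, adjusted p = 1.48e-06). Crhr1, the receptor gene for corticotropin-releasing hormone, reached 6.97 ± 0.347 from 0.423 ± 0.417 CPM (3.96 ± 0.52, adjusted p = 8.81e-05), and the cold-inducible gene Rbm3 reached 17.3 ± 3.07 from 1.36 ± 1.14 CPM (3.66 ± 0.33, adjusted p = 5.35e-06). The microglial gene Siglech had a ratio of 52.8 (counting interval 9.07 to 2130) and Myct1 of 13.9 (4.43 to 70.1).

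**Figure D1:**
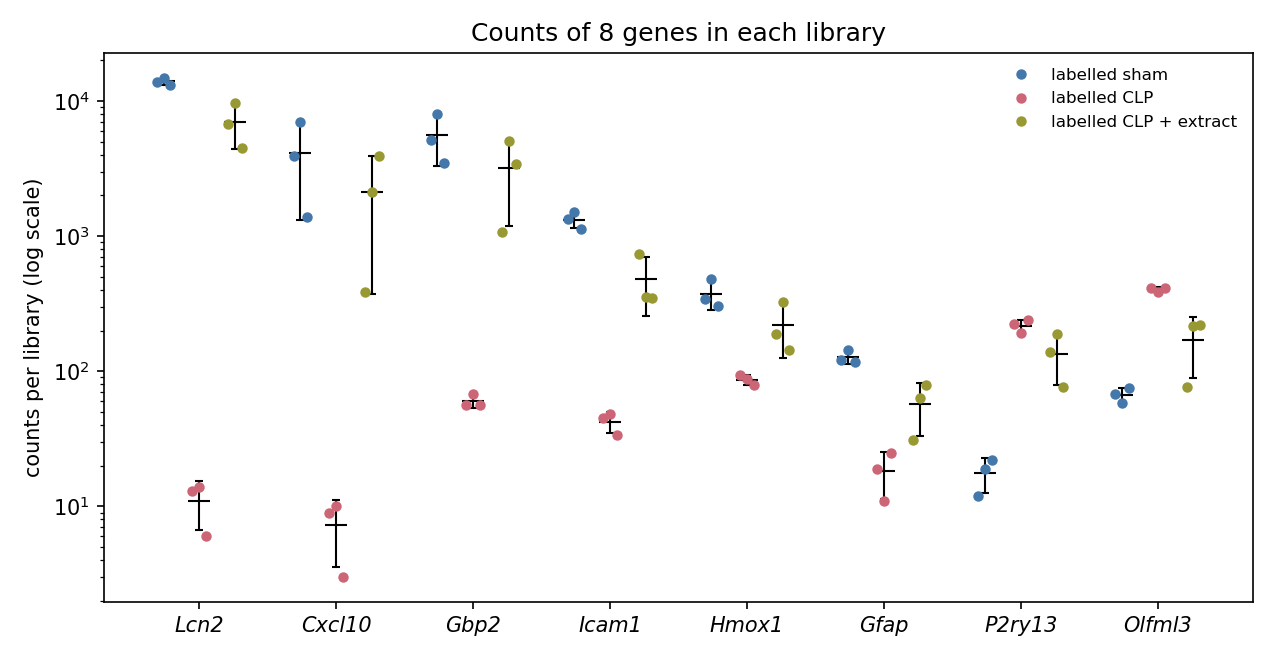
Counts per library on a log axis for Lcn2, Cxcl10, Gbp2, Icam1, Hmox1, Gfap, P2ry13 and Olfml3 in the libraries labelled sham, CLP and CLP plus extract. Points are libraries and bars are mean ± SD (n = 3).

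In all, 4318 of 8479 tested genes (50.9%) differed between libraries labelled CLP and sham, 2197 higher and 2121 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these, 700 were more than 2-fold higher and 795 more than 2-fold lower. The groups did not overlap in 4710 genes (55.5%), where chance ordering of 3 against 3 libraries gives 10%. A fit of only these 6 libraries, which leaves out the extract columns discussed further on, called 3912 of 8213 genes (1946 higher, 1966 lower). Its common dispersion was 0.00443, against 0.00711 with all 9 libraries, and Lcn2 had an adjusted p of 1.5e-15 in it.

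Genes of the pathway in the series title moved unevenly. Hmox1, which encodes haem oxygenase 1, fell from 79.3 ± 18.9 CPM in libraries labelled sham to 18.3 ± 1.76 in those labelled CLP (n = 3, log2 fold −2.11 ± 0.33, adjusted p = 0.00154), with counts of 304 to 480 and 79 to 93. Nfe2l2, the gene of the transcription factor Nrf2, fell from 95.1 ± 7.54 to 67.8 ± 12 CPM (−0.49 ± 0.11, adjusted p = 0.00287). Keap1, which encodes its repressor, fell from 17.9 ± 3.77 to 8.51 ± 1.69 (−1.07 ± 0.2, adjusted p = 0.000766). Nqo1, a target gene of Nrf2, had 20.8 ± 1.7 and 22.3 ± 2.3 CPM in the groups labelled CLP and sham (−0.1 ± 0.12, adjusted p = 0.488). The kinase subunit gene Pik3r1 fell from 94.7 ± 2.82 to 69.9 ± 10.4 CPM (−0.44 ± 0.11, adjusted p = 0.00425). Akt2 rose from 1.62 ± 0.53 to 4.49 ± 0.993 CPM (1.46 ± 0.31, adjusted p = 0.0018). Pik3ca had a log2 fold of 0.66 ± 0.3 (adjusted p = 0.0779), and 0.84 without CLP replicate 2 (adjusted p = 0.0354, range over alternatives 0.0354 to 0.334). Akt1 had 0 to 4 counts per library and was not tested.

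The list of PI3K-AKT genes held 2 higher and 4 lower among 12 tested, with Foxo1 (−0.43 ± 0.06, adjusted p = 0.000191), Irs2 (−0.75 ± 0.12, adjusted p = 0.00128) and Phlpp1 (0.3 ± 0.05, adjusted p = 0.000737) among them. Its camera test did not pass (adjusted p = 0.762), and its median of −0.02, mean of 0.02 and test direction (down) differed in sign. The list of Nrf2 regulators and target genes was lower by camera (median −0.17, adjusted p = 0.0357, adjusted p = 0.112 with an estimated correlation). It had 3 higher and 13 lower of 23 members, such as Gsr (−0.8 ± 0.12), Gclm (−0.45 ± 0.08) and G6pdx (−0.33 ± 0.06). Among genes with 1 RefSeq transcript the Nrf2 list gave an adjusted p of 0.266.

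Inflammation genes, which tissue raises in infection and injury, were lower in the libraries labelled CLP. Of the lists that follow here and in the next paragraph, 11 were taken as inflammation lists after values were seen: cytokine, NF-kB, interferon, MHC class I, acute-phase, complement, pan-reactive, A1, A2, vascular inflammation and neutrophil genes. Camera called all 11 lower, and 3 held with an estimated correlation (acute-phase, pan-reactive and vascular inflammation, each at an adjusted p of 0.0486). They share members. Lcn2 and Ptgs2 are each in 3 of them. Among those in 2 are Icam1, H2-T23, Psmb8, H2-D1, Steap4, Cp, S100a8, C3, Cxcl10, Cd14 and Fgl2. The acute-phase and pan-reactive lists, both among the 3 that held, share Lcn2, Steap4 and Cp. Of 10 tested cytokine and chemokine genes 9 were lower and 0 higher (median −6.81, camera adjusted p = 6.52e-06, adjusted p = 0.102 with an estimated correlation), with Cxcl1 at −6.62 ± 0.46 (adjusted p = 3.43e-05), Ccl5 at −7.01 ± 0.57 (adjusted p = 0.000119) and Ccl12 at −2.77 ± 0.42. Il1b, Tnf and Il6 had 0 to 2 counts per library and were not tested. Genes of NF-kB feedback and early inflammation were lower in 9 of 11, with 0 higher (median −2.09, adjusted p = 1.66e-05, adjusted p = 0.0857 with an estimated correlation). Among these were Icam1 (281 ± 39.5 to 8.96 ± 1.71 CPM, −4.97 ± 0.41), Myd88 (−1.82 ± 0.14) and Cebpd (−2.37 ± 0.16). Interferon-stimulated genes were lower in 11 of 12, with 0 higher (median −2.93, adjusted p = 6.77e-06, adjusted p = 0.0857 with an estimated correlation), as in Mx2 (−3.04 ± 0.22), Stat2 (−1.69 ± 0.17), Ifit1 (−3.8 ± 0.42) and Rsad2 (−3.79 ± 0.43). All 7 tested genes of MHC class I presentation were lower (median −2.42, adjusted p = 2.22e-05, adjusted p = 0.0799 with an estimated correlation), Psmb8 by −3.72 ± 0.2 and H2-T23 by −2.95 ± 0.14. All 11 tested acute-phase genes were lower (median −4.02, adjusted p = 6.52e-06), Steap4 by −5.6 ± 0.52 and Cp by −2.7 ± 0.35. All 7 tested complement genes were lower (median −1.63, adjusted p = 0.000414, adjusted p = 0.0799 with an estimated correlation), among them C3ar1 (−3.17 ± 0.27), C1ra (−3.99 ± 0.6) and C1qb (−0.94 ± 0.17).

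Reactive-astrocyte genes, which astrocytes raise after injury, had the same sign. Gfap, the astrocyte filament gene, fell from 27 ± 2.75 to 3.85 ± 1.41 CPM (n = 3, −2.79 ± 0.32, adjusted p = 8.18e-05). All 9 tested pan-reactive genes were lower (median −3.07, camera adjusted p = 2.38e-06), with Vim at −1.54 ± 0.09 and Hspb1 at −3.07 ± 0.21. All 5 tested A1 genes were lower (median −2.95, adjusted p = 0.00015, adjusted p = 0.0799 with an estimated correlation), as were all 6 tested A2 genes (median −2.22, adjusted p = 0.000409, adjusted p = 0.0846 with an estimated correlation), with Cd109 at −1.22 ± 0.12 and S100a10 at −1.35 ± 0.17. Of 12 vascular inflammation genes 11 were lower and 1 higher (median −2.21, adjusted p = 4.45e-05), including Vcam1 (−0.83 ± 0.08), Ch25h (−4.49 ± 0.45) and Angpt2 (−2.77 ± 0.33). Glucocorticoid-response genes were lower in 13 of 17, with 0 higher (median −1.24, adjusted p = 4.45e-05, adjusted p = 0.0857 with an estimated correlation), such as Fkbp5 (−1.32 ± 0.19), Dusp1 (−1.25 ± 0.16) and Errfi1 (−1.12 ± 0.23). Neutrophil genes were lower in 4 of 5, with 0 higher (median −4.27, adjusted p = 0.00178, adjusted p = 0.13 with an estimated correlation). S100a8 fell from 36 ± 1.45 to 0.847 ± 0.736 CPM (−5.37 ± 0.79, adjusted p = 0.00131). Ribosomal protein genes were lower in 23 of 29 and higher in 1 (median −0.26, adjusted p = 0.00015, adjusted p = 0.264 with an estimated correlation), with Rpl32 at −0.43 ± 0.05 and Rps14 at −0.27 ± 0.04.

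Lists of homeostatic microglia, oligodendrocytes, their precursors and cholesterol synthesis were higher in the libraries labelled CLP by camera. All 8 tested homeostatic microglia genes were higher (median 2.22, camera adjusted p = 0.000424, adjusted p = 0.0846 with an estimated correlation). P2ry13, a purinergic receptor gene of resting microglia, rose from 3.72 ± 1 to 45.9 ± 4.2 CPM (n = 3, 3.61 ± 0.35, adjusted p = 5.98e-05), and Olfml3 from 14.2 ± 1.85 to 85.1 ± 1.98 (2.58 ± 0.36, adjusted p = 0.000984). Of 9 oligodendrocyte genes 7 were higher and 1 lower (median 0.89, adjusted p = 0.00926, adjusted p = 0.308 with an estimated correlation), with Ermn at 1.16 ± 0.08, Opalin at 1.05 ± 0.1, Cnp at 1.11 ± 0.12 and Hapln2 at −1.38 ± 0.16. Of 7 oligodendrocyte-precursor genes 6 were higher and 1 lower (median 0.8, adjusted p = 0.0239, adjusted p = 0.19 with an estimated correlation), among them C1ql1 (1.52 ± 0.24) and Cspg4 (0.8 ± 0.13). Cholesterol-synthesis genes were higher in 7 of 10, with 0 lower (median 0.46, adjusted p = 0.00332, adjusted p = 0.0846 with an estimated correlation), such as Sc5d (1.22 ± 0.1) and Sqle (0.56 ± 0.08).

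Camera called 18 of 44 lists, 4 higher and 14 lower in the libraries labelled CLP. With an estimated correlation 3 lists held, the acute-phase, pan-reactive astrocyte and vascular inflammation lists, each at an adjusted p of 0.0486. With fry 33 lists were called.

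**Figure D2:**
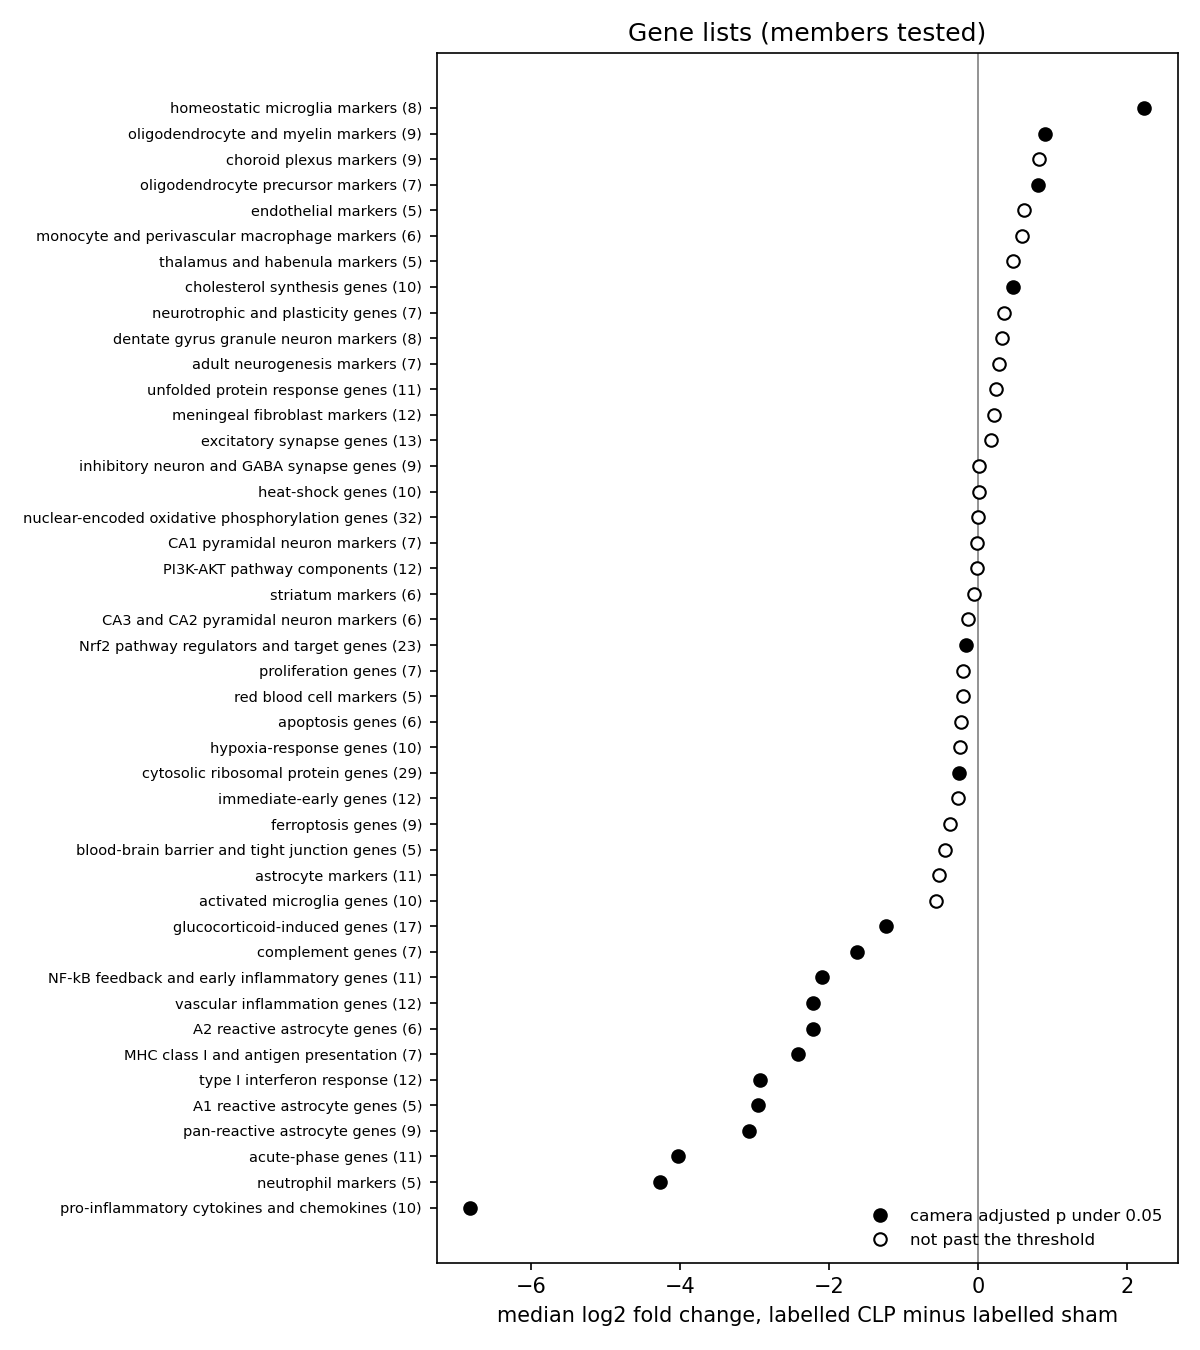
Median log2 fold, labelled CLP minus labelled sham, for the 44 lists with at least 5 tested members. Filled points have a camera adjusted p under 0.05.

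Neuronal lists were not called, though members of them differed. Of 13 excitatory synapse genes 4 were higher and 0 lower (median 0.17, camera adjusted p = 0.244). Of 9 inhibitory synapse genes 3 were higher and 2 lower (median 0.01, adjusted p = 0.858). Of 7 neurotrophic genes 4 were higher and 1 lower (median 0.34, adjusted p = 0.216), with Bdnf at 0.91 ± 0.18 and Homer1 at 1.54 ± 0.18. Activity-induced immediate-early genes had 5 higher and 5 lower of 12, or 5 and 6 adjusted over the list alone (median −0.27, mean −0.05, adjusted p = 0.808), with Npas4 at 1.58 ± 0.17, Egr4 at 0.72 ± 0.12, Dusp1 at −1.25 ± 0.16 and Klf4 at −1.02 ± 0.18. Regional markers were mixed: dentate gyrus 5 higher of 8 and 0 lower (median 0.32, adjusted p = 0.0917), CA1 2 higher and 1 lower of 7 (median −0.01, mean 0.11, adjusted p = 0.762), and CA3 and CA2 2 higher and 1 lower of 6 (median −0.14, adjusted p = 0.762). In a fit of only the 6 libraries labelled sham and CLP, CA3 and CA2 genes had 0 higher and 2 lower. Neurogenesis genes had 5 higher and 1 lower of 7 (median 0.28, adjusted p = 0.156), with Sox11 at 0.56 ± 0.11.

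Other stress and metabolism lists were not called. Unfolded-protein genes had 5 higher and 3 lower of 11 (median 0.24, mean −0.2, test direction up, adjusted p = 0.502), with Pdia6 at 0.52 ± 0.06, Atf3 at −2.13 ± 0.27 and Trib3 at −3.09 ± 0.5. Heat-shock genes had 2 higher and 2 lower of 10 (median 0.01, mean −0.33, adjusted p = 0.762), with Hspa4l at 0.4 ± 0.06 and Bag3 at −0.85 ± 0.13. Hypoxia genes had 1 higher and 5 lower of 10, or 2 and 5 adjusted over the list alone (median −0.24, adjusted p = 0.249), with Bnip3 at −0.46 ± 0.05 and Ndrg1 at 0.6 ± 0.14. Apoptosis genes had 2 higher and 2 lower of 6, or 2 and 3 over the list alone (median −0.23, adjusted p = 0.655), with Mcl1 at −0.74 ± 0.08 and Bcl2 at 0.53 ± 0.11. Ferroptosis genes had 1 higher, Alox15 at 1.18 ± 0.17, and 7 lower of 9 (median −0.38, adjusted p = 0.101). Oxidative phosphorylation genes had 2 higher and 4 lower of 32, or 1 and 3 over the list alone (median 0, adjusted p = 0.824), with Uqcrc1 at −0.22 ± 0.04. Proliferation genes had 1 higher and 2 lower of 7, or 2 and 3 over the list alone (median −0.21, adjusted p = 0.549), with Pcna at −0.4 ± 0.08. Of the short lists, the inflammasome genes Pycard (−1.82 ± 0.2) and Casp1 (−0.98 ± 0.24) were both lower, and 3 of 4 histone genes were higher, among them H1f2 (0.91 ± 0.15).

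Apart from the neutrophil list, lists of markers of tissue other than hippocampus and of blood were not called, though members of them differed. Of 9 choroid plexus genes 4 were higher and 0 lower (median 0.81, camera adjusted p = 0.0613), and Sostdc1 rose from 7.76 ± 0.287 to 62.3 ± 24.2 CPM (n = 3, 3 ± 0.43, adjusted p = 0.00105). Of 12 meningeal genes 5 were higher and 1 lower (median 0.21, adjusted p = 0.502), with Ogn at 1.71 ± 0.26 and Slc22a6 at 2.88 ± 0.54. Red blood cell genes had 0 higher and 2 lower of 5 (median −0.21, adjusted p = 0.488), Hbb-bs at 319 ± 5.17 and 276 ± 27.1 CPM in sham-labelled and CLP-labelled libraries (−0.21 ± 0.06, adjusted p = 0.0122). Striatal genes had 1 higher and 2 lower of 6 (median −0.06, mean 0.03, adjusted p = 0.655), with Rgs9 at −0.79 ± 0.09. Thalamic genes had 2 higher and 1 lower of 5 (median 0.46, adjusted p = 0.792), with Ntng1 at 2.26 ± 0.32. Monocyte genes had 3 higher and 2 lower of 6 (median 0.58, adjusted p = 0.762), with Mrc1 at 1.47 ± 0.19 and Lyve1 at −1.71 ± 0.28.

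Other cell-type lists stayed uncalled. Activated microglia genes had 1 higher and 6 lower of 10, or 1 and 7 over the list alone (median −0.56, camera adjusted p = 0.0917), with Cst7 at −2.97 ± 0.52 and Ctsb at −0.47 ± 0.09. Aif1, a microglial marker gene, had 0 to 1 counts per library and was not tested. Astrocyte genes had 3 higher and 7 lower of 11 (median −0.53, adjusted p = 0.244), with Gja1 at 1.12 ± 0.14 and Slc1a3 at −0.19 ± 0.03. Blood-brain barrier genes had 1 higher and 4 lower of 5 (median −0.45, adjusted p = 0.156), with Cldn5 at −1.05 ± 0.1. Endothelial genes had 3 higher and 1 lower of 5, or 4 and 1 over the list alone (median 0.61, adjusted p = 0.244), with Itm2a at 2.23 ± 0.28 and Flt1 at 0.61 ± 0.09. Pericyte genes were higher in 2 of 4, among them Rgs5 (0.83 ± 0.05), ependymal genes in 3 of 4, among them Enkur (1.16 ± 0.22), and neocortex genes in 1 of 2, Fezf2 (1.1 ± 0.18). Hypothalamus genes had 0 of 2 called. Mitochondrially encoded genes and lymphocyte genes had 0 tested members.

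Long-used reference genes were nearly absent from the table. Actb had a mean of 0.11 counts per library, Gapdh 2.22, Camk2a 0, Grin1 0, Gria2 0.44 and Mbp 2.44, whereas Slc17a7, a gene of excitatory neurons, had 28325.11 and Cst3 13754.89. The 7993 coding genes with 1 RefSeq transcript held 89.9% of coding counts, and 43.7% of them had a mean of at least 10. Of the 13907 coding genes with several transcripts 22.4% did. Akt1 (mean 2 counts) and Aif1 (0.11) could not be tested in this table. Several named genes have more than 1 RefSeq transcript, such as Akt2 (11), Siglech (15), Crhr1 (8), Gfap (4), Bicd2 (4) and Keap1 (4). Which of their transcripts were counted in full is not known, so their folds may not stand for the whole gene. Xist had 0 to 3 counts in every library, while the Y-linked genes Eif2s3y and Uty had 4 to 20 and 5 to 22, Ddx3y had 1 to 7 and Kdm5d 0. Uty had 20 to 22 counts with the sham label, 5 to 8 with the CLP label and 12 to 18 with the extract label. Eif2s3y (13 to 20 and 4 to 16) and Ddx3y (4 to 7 and 1 to 4) overlapped between the sham and CLP labels.

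**Figure D3:**
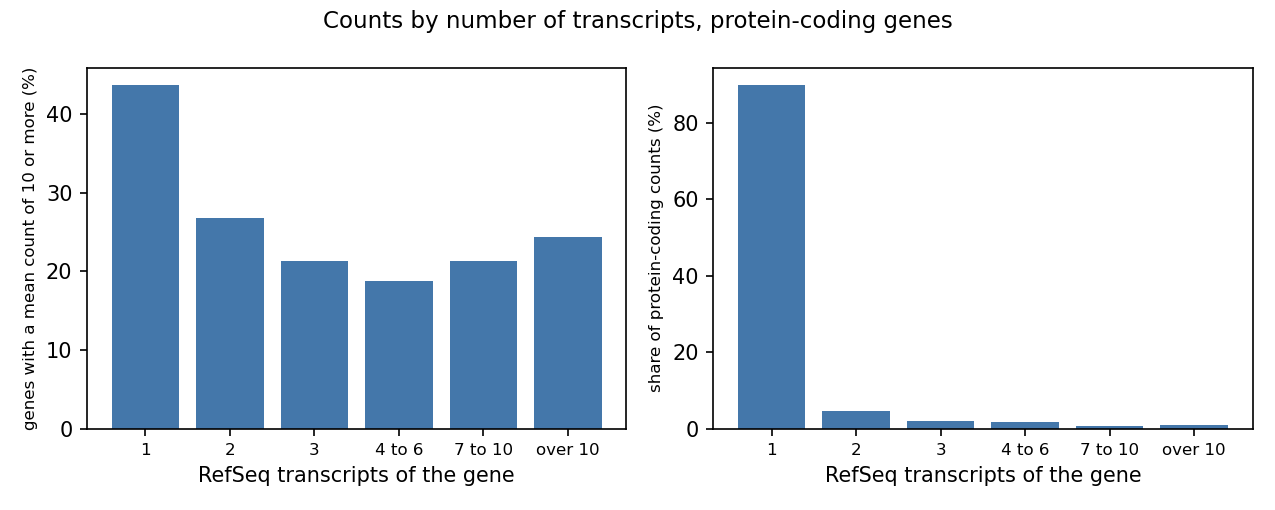
Left, percent of protein-coding genes with a mean of at least 10 counts; right, share of coding counts, each by the gene's number of RefSeq transcripts. Bars are all 9 libraries together.

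Counts in the libraries labelled CLP plus extract lay between the medians of the other groups wherever those medians differed. In each of the 3, all 20319 transcripts whose sham and CLP medians differed had a count from the lower to the higher median (100%). The same measure for each library labelled sham or CLP, between the medians of the groups it was not in, gave 29.63% to 33.57% of 16525 or 16575 transcripts. As the extract medians lie between the others, such libraries fall mostly outside by construction. Their share is therefore no reference for a middle group. Simulated extract libraries counted from the mean of the groups had 71.98% to 72.59% between the medians. Where the sham and CLP medians were equal and above 0, in 2230 transcripts, every extract count ran from 1 to that median. Of 239 genes called against both groups 210 lay between them, 0 were higher than both and 29 were lower than both. Of those 29, 21 (72.4%) had equal medians, against 1.93% of tested genes. Zfp593, for example, had a median of 55 counts in both groups and 7 to 14 counts in the extract libraries. Among transcripts with mean counts from 100 to 400 and medians 1 to 5 counts apart, the SD between libraries was 1 count in the extract group, 13.32 in the sham group and 14.15 in the CLP group, where counting alone gives 12.85. No extract library had a count for any of the 90211 transcripts at 0 in the other 6. Every library labelled sham or CLP had counts for 903 to 1031 transcripts found in no other library of those 6. Over 2550 transcripts with medians at least 50 apart, positions between the medians were evenly spread in each extract library (chi-square p = 0.822, 0.607 and 0.403). Correlations of position between pairs of extract libraries were −0.015, −0.021 and 0.023. P-values with the extract group, given in what follows, therefore do not measure spread between animals. The fit of all 9 libraries also drew its dispersion from these columns, so the SE and p-values given for CLP against sham carry part of this limit. Numbers of list members called carry it too. In the fit of only the 6 libraries labelled sham and CLP, which tested 8213 genes, acute-phase genes had 10 lower and complement genes 6. Glucocorticoid genes had 11 lower there, ferroptosis genes 5 and hypoxia genes 3. Choroid plexus genes had 2 higher, and CA3 and CA2 genes 0 higher and 2 lower.

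**Figure D4:**
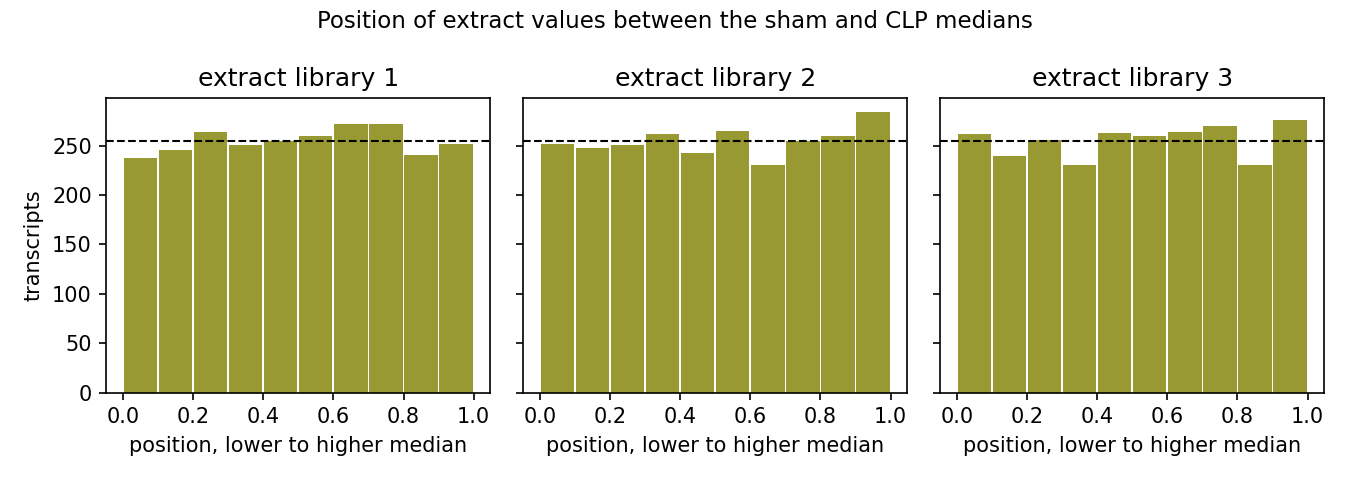
Position of the count from the lower (0) to the higher (1) of the sham and CLP medians, in 10 bins, for 2550 transcripts in each of the 3 libraries labelled CLP plus extract. Bars are numbers of transcripts and the dashed line is an even spread.

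Lcn2 was higher in the libraries labelled CLP plus extract than in those labelled CLP, at 1480 ± 543 against 2.33 ± 0.955 CPM (n = 3, log2 fold 9.3 ± 0.48, adjusted p = 0.00017 by edgeR's quasi-likelihood test). So were Psmb8, an immunoproteasome gene (107 ± 25.6 against 11.3 ± 1.19 CPM, 3.25 ± 0.2, adjusted p = 1.96e-05), and the MHC class I gene H2-T23 (136 ± 28.6 against 32.4 ± 1.31, 2.07 ± 0.14, adjusted p = 1.84e-05). Lower with the extract label were the immediate-early gene Npas4 (−1.32 ± 0.16, adjusted p = 0.000333) and the cholesterol-synthesis gene Sc5d (−0.73 ± 0.09, adjusted p = 0.000411). Of all tested genes, 601 were higher and 355 lower, 956 in total (11.3%), 269 and 80 of them more than 2-fold. Without CLP replicate 1, 2 or 3 the number of genes called was 515, 501 or 542.

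Hmox1 was at 46.3 ± 19.9 CPM with the extract label against 18.3 ± 1.76 with the CLP label (n = 3, 1.34 ± 0.34, adjusted p = 0.0479). The call of Hmox1 was lost in 7 of 19 alternatives, in a range of 8e-06 to 0.133. These were no filter (adjusted p = 0.111), the filter of 1 CPM (0.063), and leaving out sham replicate 1 (0.0646), CLP replicate 1 (0.107), 2 (0.112) or 3 (0.133), or CLP plus extract replicate 1 (0.0974). Keap1 rose to 16 ± 1.9 from 8.51 ± 1.69 CPM (0.91 ± 0.2, adjusted p = 0.0114), but had 0.0583 without CLP replicate 2, the top of a range from 3.35e-06. Gfap rose to 12.2 ± 5.18 from 3.85 ± 1.41 CPM (1.65 ± 0.35, adjusted p = 0.0143), with 0.0604 without CLP replicate 1 and 0.0569 without CLP replicate 2 (range 3.55e-13 to 0.0604). Not called were Nfe2l2 (0.12 ± 0.11, adjusted p = 0.533), Nqo1 (−0.01 ± 0.12, 0.969), Pik3ca (−0.12 ± 0.27, 0.817), Pik3r1 (0.17 ± 0.11, 0.331) and Akt2 (−0.78 ± 0.28, 0.0893). The PI3K-AKT list had 2 higher of 12, or 3 higher and 1 lower over the list alone (median 0.04, camera adjusted p = 0.583). The Nrf2 list had 4 higher of 23 (median 0.11, adjusted p = 0.0938).

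Lists lower with the CLP label were mostly higher with the extract label, 13 lists higher and 4 lower by camera. These directions follow from the position of the extract counts between the medians and are no separate finding. With an estimated correlation 6 of these list calls held. They were pan-reactive astrocyte genes (9 higher of 9, median 2.43, adjusted p = 2.44e-10), acute-phase genes (9 of 11, or 10 over the list alone, median 3.63, adjusted p = 2.61e-09) and MHC class I genes (6 of 7, median 1.24, adjusted p = 2.01e-07). The others were A1 genes (4 of 5, median 2.07, adjusted p = 1.4e-06), vascular inflammation genes (6 of 12, or 8 over the list alone, median 1.19, adjusted p = 5.83e-06) and complement genes (3 of 7, or 6 over the list alone, median 1.06, adjusted p = 7.49e-05). Cytokine genes were higher in 5 of 10, or 8 over the list alone, among them Cxcl1 (5.43 ± 0.5) and Ccl5 (6.11 ± 0.61) (median 5.45, adjusted p = 5.29e-09, adjusted p = 0.0631 with an estimated correlation). Interferon genes were higher in 6 of 12, or 11 over the list alone (median 2.07, adjusted p = 1.7e-07, adjusted p = 0.0631 with an estimated correlation). NF-kB genes were higher in 6 of 11, or 8 over the list alone (median 1.52, adjusted p = 2.39e-06, adjusted p = 0.068 with an estimated correlation). Glucocorticoid genes were higher in 5 of 17, or 8 over the list alone (median 0.69, adjusted p = 1.27e-05, adjusted p = 0.068 with an estimated correlation). Neutrophil genes were higher in 3 of 5, or 4 over the list alone (median 3.03, adjusted p = 1.75e-05, adjusted p = 0.0643 with an estimated correlation). A2 genes were higher in 5 of 6 (median 1.33, adjusted p = 5.29e-05, adjusted p = 0.0631 with an estimated correlation). Ribosomal genes were higher in 7 of 29, or 15 over the list alone (median 0.13, adjusted p = 0.000922, adjusted p = 0.305 with an estimated correlation). Lower were cholesterol genes (4 of 10, median −0.15, adjusted p = 0.00575, adjusted p = 0.068 with an estimated correlation) and homeostatic microglia genes (1 of 8, or 6 over the list alone, median −0.53, adjusted p = 0.0046, adjusted p = 0.112 with an estimated correlation). Oligodendrocyte genes had 3 lower and 1 higher of 9, or 4 and 1 over the list alone (median −0.24, adjusted p = 0.0248, adjusted p = 0.361 with an estimated correlation). Precursor genes had 2 lower of 7, or 3 lower and 1 higher over the list alone (median −0.49, adjusted p = 0.0435, adjusted p = 0.224 with an estimated correlation).

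Among lists that camera did not call in this comparison, astrocyte genes had 4 higher and 1 lower of 11, or 5 and 2 over the list alone (median 0.2, adjusted p = 0.146). Excitatory synapse genes had 3 lower of 13, or 5 over the list alone (median −0.07, adjusted p = 0.11). Neurogenesis genes had 2 lower of 7, or 3 over the list alone (median −0.17, adjusted p = 0.101). Unfolded-protein genes had 2 higher and 1 lower of 11, or 2 and 3 over the list alone (median −0.14, mean 0.24, adjusted p = 0.592). Hypoxia genes (2 of 10, adjusted p = 0.472), heat-shock genes (2 of 10, median −0.03, mean 0.23, adjusted p = 0.592) and striatal genes (2 of 6, median −0.04, test direction up, adjusted p = 0.649) had higher members only. Ferroptosis genes had 1 higher of 9, or 1 higher and 1 lower over the list alone (adjusted p = 0.199). Blood-brain barrier genes had 1 higher of 5 (adjusted p = 0.199), and endothelial genes 1 higher and 1 lower of 5 (adjusted p = 0.507). Apoptosis genes had 1 higher of 6, or 2 higher and 1 lower over the list alone (adjusted p = 0.583). Monocyte genes had 1 higher of 6, or 1 and 1 over the list alone (adjusted p = 0.941). Immediate-early genes had 1 lower of 12, or 2 over the list alone (median 0.15, mean −0.03, adjusted p = 0.86). CA1 genes had 1 lower of 7 (median 0.03, mean −0.08, adjusted p = 0.592), and neurotrophic genes 1 lower of 7, or 2 lower and 1 higher over the list alone (adjusted p = 0.302). Pericyte genes had 1 lower of 4. Other lists had 0 called members. Over the list alone, thalamus genes had 1 higher and 1 lower of 5 (adjusted p = 0.777), and CA3 and CA2 genes 1 higher of 6 (adjusted p = 0.858).

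Against the libraries labelled sham, Bicd2 was higher with the extract label, at 7.49 ± 0.646 against 0.49 ± 0.235 CPM (n = 3, 3.85 ± 0.31, adjusted p = 3.5e-05 by edgeR's quasi-likelihood test), as were Rbm3 (12.8 ± 1.6 against 1.36 ± 1.14, 3.23 ± 0.35, adjusted p = 0.000156) and the microglial gene P2ry13 (28.5 ± 11.8 against 3.72 ± 1, 2.92 ± 0.36, adjusted p = 0.00157). Tmem154 was lower (2.68 ± 1.07 against 14.1 ± 0.822 CPM, −2.38 ± 0.22, adjusted p = 6.4e-05), as were the early-response gene Ier3 (−2.09 ± 0.23, adjusted p = 0.000666) and the adaptor gene Myd88 (−1.45 ± 0.14, adjusted p = 6.4e-05). In total 852 genes (10%) were called, 499 higher and 353 lower, 149 and 85 of them more than 2-fold. Without sham replicate 1 or 2 the number called was 404 or 352, and a fit of only the 6 libraries compared called 502.

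Lcn2 was not called in this comparison (1480 ± 543 and 2960 ± 176 CPM, n = 3, −1 ± 0.26, adjusted p = 0.066). In 4 of 19 alternatives Lcn2 was: limma-voom (0.00524), the DESeq2 Wald test (0.023), the replicate block (0.039) and without CLP plus extract replicate 2 (0.0179), in a range of 0.00524 to 0.163. Hmox1 had −0.78 ± 0.3 (adjusted p = 0.149). Hmox1 was called in 3 of 19 alternatives, the DESeq2 Wald test (0.0229), the replicate block (0.00672) and without CLP plus extract replicate 2 (0.00262), in a range of 0.00262 to 0.407. Nfe2l2 had −0.37 ± 0.11 (adjusted p = 0.0507), and was called in 9 of 18 alternatives (range 0.00186 to 0.195). These were DESeq2 size factors (0.0461), the DESeq2 Wald test (0.0496), no filter (0.00186), the filter of 1 CPM (0.0473), only the 6 libraries compared (0.034), removal of mitochondrial, haemoglobin and choroid plexus genes (0.0471), and leaving out CLP replicate 1 (0.0372), CLP replicate 3 (0.0202) or CLP plus extract replicate 3 (0.0482). Pik3r1 had −0.27 ± 0.11 (adjusted p = 0.125), and 0.038 without CLP plus extract replicate 2 (range 0.038 to 0.3). Keap1 (−0.16 ± 0.18, adjusted p = 0.626) and Nqo1 (−0.11 ± 0.12, adjusted p = 0.588) were not called. Gfap was lower at 12.2 ± 5.18 against 27 ± 2.75 CPM (−1.14 ± 0.26, adjusted p = 0.022), but had 0.0524 in only the 6 libraries compared, 0.0731 without sham replicate 1 and 0.0867 without sham replicate 2 (range 5.85e-10 to 0.0867).

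Camera called 18 lists against sham, 5 higher and 13 lower with the extract label, and 0 held with an estimated correlation. For lists also called for CLP against sham, the direction follows from the position of the extract counts and is no separate finding. NF-kB genes were lower in 3 of 11, or 6 over the list alone (median −0.53, adjusted p = 0.000229, adjusted p = 0.136 with an estimated correlation). Pan-reactive astrocyte genes were lower in 3 of 9, or 5 over the list alone (median −0.94, adjusted p = 0.000334, adjusted p = 0.11 with an estimated correlation), with Vim at −0.77 ± 0.09. MHC class I genes were lower in 2 of 7, or 4 over the list alone (median −0.67, adjusted p = 0.000334, adjusted p = 0.11 with an estimated correlation), with H2-T23 at −0.88 ± 0.12. Vascular inflammation genes were lower in 3 of 12, or 5 over the list alone (median −0.72, adjusted p = 0.000779, adjusted p = 0.11 with an estimated correlation). Interferon genes were lower in 1 of 12 (median −0.7, adjusted p = 0.000848, adjusted p = 0.181 with an estimated correlation). Glucocorticoid genes were lower in 1 of 17 (median −0.53, adjusted p = 0.00112, adjusted p = 0.163 with an estimated correlation). Ribosomal genes were lower in 3 of 29 (median −0.1, adjusted p = 0.00119, adjusted p = 0.325 with an estimated correlation). Cytokine genes were lower in 2 of 10, or 5 over the list alone (median −1.13, adjusted p = 0.00121, adjusted p = 0.237 with an estimated correlation). Complement genes were lower in 2 of 7, or 3 over the list alone (median −0.58, adjusted p = 0.00254, adjusted p = 0.11 with an estimated correlation), A1 genes in 1 of 5, or 2 over the list alone (median −0.8, adjusted p = 0.00344, adjusted p = 0.129 with an estimated correlation). A2 genes were lower in 2 of 6, or 5 over the list alone (median −0.68, adjusted p = 0.00458, adjusted p = 0.153 with an estimated correlation). Acute-phase genes had 0 of 11 called (median −0.68, adjusted p = 0.00524, adjusted p = 0.11 with an estimated correlation), and the Nrf2 list 1 higher and 1 lower of 23, or 1 and 2 over the list alone (median −0.09, adjusted p = 0.0423, adjusted p = 0.154 with an estimated correlation).

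Higher against sham were homeostatic microglia genes (3 of 8, or 7 over the list alone, median 1.13, camera adjusted p = 0.000334, adjusted p = 0.11 with an estimated correlation) and cholesterol genes (4 of 10, or 6 over the list alone, median 0.27, adjusted p = 0.00458, adjusted p = 0.11 with an estimated correlation), with Msmo1 at 0.4 ± 0.05. Oligodendrocyte genes had 4 higher and 1 lower of 9, or 6 and 1 over the list alone (median 0.37, adjusted p = 0.00519, adjusted p = 0.306 with an estimated correlation), with Ermn at 0.93 ± 0.08. Precursor genes had 2 higher of 7, or 4 over the list alone (median 0.32, adjusted p = 0.0161, adjusted p = 0.181 with an estimated correlation), and choroid plexus genes 1 of 9 (median 0.31, adjusted p = 0.0423, adjusted p = 0.6 with an estimated correlation). The PI3K-AKT list had 0 of 12 called, or 1 higher and 1 lower over the list alone (adjusted p = 0.93).

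Uncalled lists in the comparison of the extract label with sham had few called members. Neurotrophic genes had 3 higher of 7 (median 0.16, camera adjusted p = 0.161), unfolded-protein genes 2 higher of 11, or 3 over the list alone (adjusted p = 0.503). Astrocyte genes had 2 higher and 1 lower of 11 (adjusted p = 0.694) and histone genes 2 higher of 4, or 3 over the list alone. Immediate-early genes had 1 higher and 2 lower of 12, or 2 and 2 over the list alone (adjusted p = 0.694). Endothelial genes had 1 higher and 1 lower of 5, or 3 and 1 over the list alone (adjusted p = 0.167). Heat-shock genes (10 tested, adjusted p = 0.762) and CA1 genes (7 tested, adjusted p = 0.792) each had 1 higher and 1 lower. A further 9 lists had 1 member higher and 0 lower: dentate gyrus (of 8, adjusted p = 0.0792), ferroptosis (of 9, 0.139), meningeal (of 12, or 3 over the list alone, 0.403), neurogenesis (of 7, 0.403), excitatory synapse (of 13, 0.675), monocyte (of 6, 0.694), thalamus (of 5, median −0.04, mean 0.21, 0.842), pericyte (of 4) and neocortex (of 2). Ferroptosis and thalamus genes also had 1 lower over the list alone. The 6 lists with 1 member lower and 0 higher were activated microglia (of 10, adjusted p = 0.075), blood-brain barrier (of 5, 0.161), striatum (of 6, or 2 over the list alone, 0.503), apoptosis (of 6, 0.669), proliferation (of 7, 0.762) and inflammasome (of 2). Neutrophil genes had 0 of 5 called, or 2 lower over the list alone (adjusted p = 0.102), and ependymal genes 0 of 4, or 1 higher over the list alone.

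Folds with the extract label against CLP ran opposite to folds with the CLP label against sham: 4303 of the 4318 called genes (99.65%) had opposite signs, Lcn2 and P2ry13 among them. Across 8479 genes the correlation was −0.906 (Spearman −0.914), where genes are not independent replicates. Simulations with no difference between groups gave −0.5 (−0.524 to −0.458) because both folds use the CLP libraries. The covariance was −0.641 against a simulated −0.027. Genes called in both comparisons with sham numbered 818, of which 499 were higher in both, 319 lower in both and 0 opposite. Independent overlap would give 129.3 higher and 88.3 lower. Without sham replicate 1 or 2 the shared genes numbered 387 or 339. In 20 simulations with no difference between groups 0 genes were called at all, so these gave no overlap to compare with. Part of the excess in overlap may come from the shared control libraries, since no group could be split into parts of at least 2 libraries. Counts of the extract group lay between the medians of the others for every transcript whose medians differed. Opposite signs, shared calls in the same direction against sham, and list calls in the matching directions follow from that position and are no separate finding.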

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

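Only genes with counts in this table could be tested, and genes with several transcripts mostly could not. Each group had 3 libraries. For CLP against sham, a fit of genes with 1 RefSeq transcript, chosen after values were seen, called 2804 of 4908 genes. Other alternatives called 3267 to 5011, and leaving out each library 3816 to 4241. Lists called were 3 with an estimated correlation, 33 with fry and 15 to 19 otherwise, or 17 to 19 with each library left out.

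For the extract label against CLP, 1553 genes were called with no filter, 666 to 959 in other alternatives and 501 to 911 with each library left out (515, 501 and 542 without CLP replicates 1, 2 and 3). Lists called were 6 with an estimated correlation. Against sham, 1450 genes were called with no filter, 502 with only the 6 libraries compared, 566 with 1 RefSeq transcript, 709 to 860 otherwise and 352 to 834 with each library left out (404 and 352 without sham replicates 1 and 2). Lists called were 0 with an estimated correlation. The cause of these differences was not tested.

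Genes shared by the comparisons with sham were 1329 at a threshold of 0.1 and 683 to 810 in other alternatives. With each library left out they were 339 to 792 (387 and 339 without sham replicates 1 and 2). The correlation of opposite folds was −0.939 to −0.906, and −0.909 to −0.879 with each library left out. The replicate block called 4181, 908 and 840 genes and 19, 17 and 18 lists, with a correlation of −0.906 and 810 shared genes. Correlations between libraries of the same replicate number were −0.026 to 0.032, with 0 of 9 over 0.1.

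Of 3647 values of 196 named genes over the alternatives for CLP against sham, 68 lost and 17 gained a call. Against CLP the extract label had 261 lost and 59 gained of 2622, and against sham 238 lost and 113 gained of 3040, with 0 called values reversed in sign. Of values not called, 3, 9 and 2 changed sign in these comparisons.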

Other observations

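Gene families formed by shared name stems were tested in the 6 libraries labelled sham and CLP, a test chosen after results were seen. Translation initiation genes (Eif) were lower with the CLP label in 18 of 34 members, with 1 higher (median log2 fold −0.37, limma's camera adjusted p = 0.0112). Ribosomal genes were lower in 20 of 26 Rps members, with 1 higher (median −0.25, adjusted p = 0.0127), and in 22 of 34 Rpl members, with 2 higher (median −0.18, adjusted p = 0.0226). Proteasome lid and base genes (Psmd) were lower in 9 of 10, with 0 higher (median −0.26, adjusted p = 0.0226), and chemokine genes (Ccl) in 7 of 9, with 1 higher (median −2.78, adjusted p = 0.0379). Of 96 families these 5 were called, and each had an adjusted p of 0.92 with an estimated correlation.

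All tests of the extract columns were set down after results were seen. In the libraries labelled CLP plus extract every transcript whose sham and CLP medians differed had a count between them. Separate libraries with intermediate expression are argued against, since simulated ones had 71.98% to 72.59% of transcripts there and these had 100%. Sham and CLP material mixed in 1 share per library is argued against as well: among transcripts of mean count 100 to 400 with medians 1 to 5 apart the SD between the 3 libraries was 1 count, below the 12.85 that counting alone gives, while the spread of positions across transcripts (interquartile range 0.43 to 0.533, against 0.048 to 0.386 in libraries labelled sham or CLP) decided nothing. Whole numbers drawn evenly between the medians of the other 6 libraries could give such columns, as positions were evenly spread (lowest chi-square p = 0.403). How these columns came about stays open, because raw reads were not analysed here.

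The tests of the labels were also set down after results were seen. Inflammation genes were higher and homeostatic microglia genes lower in the libraries labelled sham, with 11 of 11 inflammation lists lower with the CLP label, 3 of them also with an estimated correlation. An exchange of the names sham (CTL) and CLP (SAE) stays open, as this count restates the pattern and does not test it. Blood or other tissue carried into the libraries labelled sham is argued against as the whole cause by the homeostatic microglia median of 2.22. Added RNA would dilute resident transcripts alike. For the higher inflammation genes alone this median decides nothing, since added RNA could raise them whatever the microglia genes do. Inflammation in sham-operated mice with labels as given stays open too: the highest Lcn2 count in a library labelled CLP was 14, and no library of untreated mice was at hand. Such inflammation would not by itself account for the low counts with the CLP label, such as Cxcl10 (3 to 10) and Icam1 (34 to 48). Records of the surgery or a record of the tubes could decide between these explanations.

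The tests of the few counts in genes with several RefSeq transcripts came after results were seen as well. Genes with 1 RefSeq transcript held 89.9% of coding counts. Reads that match several transcripts may have been left uncounted, but this share restates the pattern and is no test of it. Low expression in hippocampus stays open for these genes as a whole. The highest mean among 7 brain genes with several transcripts was 12.44 counts (Snap25), but these 7 were picked after values were seen. Apoe (mean 51.78 counts) and Syn1 (41), also with several transcripts, were outside the 7. Grin2a (4133 to 5477) and Ctsb (1954 to 2814), each with 2 transcripts, had many counts. Whether reads were left out, and at which step, stays open.

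Splits of the libraries were also chosen after results were seen, and 10 splits are too few for a share under 0.05. In each comparison only 1 of 10 splits, the labelled grouping, called as many genes: 4318 for CLP against sham (highest other 0), 3912 in the 6 libraries alone (highest other 0), 956 for the extract label against CLP (highest other 0) and 852 against sham (highest other 0).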
